A study of Mus musculus with 29 samples.

How the data were processed

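The series measured translation and N6-methyladenosine (m6A), a methylated base in mRNA, in mouse embryonic fibroblasts (MEF) and in mouse liver. Ribo-seq sequences the mRNA fragments that ribosomes protect, called footprints. In m6A-seq, fragmented RNA is immunoprecipitated (IP) with antibodies against m6A, and RNA-seq of the same fragmented RNA before the IP serves as input. The 29 libraries fell into 22 groups by their labels, with at most 2 libraries in a group. MEF were kept in complete medium (sufficient) or starved for 2 h, and livers came from fed mice or from mice fasted for 18 h. The MEF labels read AA starvation, taken here as starvation of amino acids. Per the labels, the lines were MEF with no knockdown named (plain), MEF with a scrambled hairpin (shScram), MEF with a hairpin against ALKBH5 (shALKBH5), wild-type liver, and liver with FTO overexpression (FTO_OE). ALKBH5 and FTO are enzymes that remove methyl groups from m6A. The series' design text also names QTI-seq, which was not analysed here.

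The Ribo-seq files held deposited counts, as whole numbers of footprints at each position of a transcript. The files of the IP and input libraries held deposited coverage signal, the number of reads over each nucleotide of a transcript, with no scaling to depth visible in the values. The smallest total of a transcript in a coverage file was 15, which is 1 read of that length. The submitters' processing notes name cutadapt, Bowtie and the mouse build GRCm38, with no version or role. The transcript set, the rule for reads with several matches, the use of strand and the read filters are not given in the sources used here, so transcripts that share sequence can share reads. Each file held 1 library, and rows were Ensembl transcript identifiers with no gene names.

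No table that pairs transcript identifiers with genes was used here, so no gene names, gene coordinates or tests of the 27 lists of gene symbols fixed in advance are given. FTO, ALKBH5 and ATF4 transcripts could not be checked for the same reason, and the labels of the overexpression and the knockdown therefore stand without a check. For each comparison the rule for named transcripts took the largest rises and falls among transcripts past the test, with an average log2 level of at least 3 and no overlap between the libraries of the 2 groups. For translational efficiency and the leader ratio overlap was not examined, and for the leader ratio the level was not applied. The rule was shortened from 8 to at most 2 rises and 2 falls, because the identifiers carry no names. For single-library comparisons the rule took the largest differences among transcripts with at least 10 reads in each library and 100 in all.

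The boundaries of the translated region were inferred from the footprints, because no annotation was used. Footprints of 10 Ribo-seq libraries were pooled, and the stretch of codons that best separated dense from sparse footprints was taken as the translated region of each transcript with at least 200 pooled footprints. A region was found for 10976 of 11062 such transcripts, and 7576 were kept with at least 50% of footprints inside and at least 45% in 1 reading frame. In simulated transcripts the inferred start lay within 6 nt of the true one in 91% and within 30 nt in 99.8% of 1000 transcripts. The part before the region is called the leader and the part after it the trailer. Leaders were measured in the 4551 transcripts with a leader of at least 60 nt.

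Footprints on the translated region were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr and the quasi-likelihood test, in 1 fit over the 8 liver libraries. Signal was tested with limma 3.58.1 (limma-trend) on log2(signal per 1000000 + 1) with TMM factors, over transcripts with a mean of at least 1 on that scale. Fold changes of signal are on that scale, which understates changes of low transcripts. Translational efficiency is the footprint level relative to the input level. It was tested as an interaction in limma on log2(value per 1000000 + 1), and not in edgeR as designed, because the input files hold coverage. IP enrichment over input was an interaction in the same kind of fit. Input libraries of liver had 1 library per group, so fasting and FTO_OE were fitted as additive effects and any interaction counted as error. The 6 MEF IP libraries were fitted with line and starvation as additive effects. Lone libraries were assumed to vary like the others. Calls are transcripts with a Benjamini-Hochberg adjusted p below 0.05. The share of signal on the leader was compared by two-sided exact permutation tests. The leader ratio, log2 of leader signal over the rest of the transcript with a pseudocount of 1, was tested in limma for transcripts with at least 5 per 1000000, and this measure was added after the files were seen. Groups, tests, covariates and the first list of alternatives were fixed before the data were examined. The alternatives were other size factors, other filters and pseudocounts, DESeq2 1.42.0 for the footprint counts, the replicate number as a block, whole transcripts, and each library left out. The removal of the tallest 60 nt window of each transcript was added later. Figures were drawn with matplotlib 3.10.9, and shares were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

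The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. In the liver IP libraries, the deviations of replicate 2 from replicate 1 correlated across transcripts between groups, with Pearson's r of 0.159, 0.260 and 0.483 for the 3 pairs of groups. The numbers were therefore examined as a pairing of the IP libraries, with the number 2 taken from the titles and the number 1 from the accession order. The main IP fits and the permutation tests left this pairing out, and the number entered as a block in an alternative fit alone. The fit with the number as a block is given where it changed a call.

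Total footprints per library ran from 732452 to 13215473 in liver and were 10753915 and 4563879 in MEF. Coverage libraries held about 1520000 to 27000000 reads, estimated from the signal and the median width of isolated reads. 1 transcript, ENSMUST00000038863, took 17.3% to 62.1% of the signal in the 19 coverage libraries. Wilson intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

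The tests were tried on simulated data with known changes. For fasting footprints in wild type, 7424 transcripts were drawn at their fitted dispersions, and 13.4% of changes of 1, 73.1% of changes of 2 and 98.5% of changes of 4 on the log2 scale were called. For signal the answer depended on the spread assumed. With the moderated SD of each transcript, changes of 2 were called in 94.0% for MEF starvation, 92.5% for shALKBH5 and 100% for input FTO_OE. The enrichment fit called 13.4% and the translational efficiency fit 10.4% of changes of 2, and 0% of changes of 1 in both. With the unmoderated SD of each transcript, the input fit called 0% of changes of 4, and the enrichment fit called 24.2% of them. Of 200 calls in the simulated input FTO_OE fit with the moderated SD, 22 were of unchanged transcripts, a share above the nominal 5%.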

Results

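m6A IP signal and input RNA signal were measured along mouse transcripts in sufficient and starved MEF and in fed and fasted liver. Ribosome footprints were measured in fed and fasted liver and, in MEF, in sufficient cells alone. For liver there were 2 Ribo-seq libraries for each of the 4 combinations of fed or fasted with wild type or FTO_OE. There were 2 IP libraries each for wild-type fed, wild-type fasted and FTO_OE fed liver and 1 for FTO_OE fasted liver, with 1 input library for each of the 4. For MEF there was 1 IP library for each of 3 lines in each state, 1 input library for each state of plain cells, and 1 Ribo-seq library each for sufficient shScram and sufficient shALKBH5 cells. The FTO_OE fed replicate 2 library was the shallowest Ribo-seq library, at 732452 footprints, and FTO_OE fasted replicate 1 the deepest, at 13215473.

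The 3 assays had different profiles along the transcript. Footprints filled the translated region and were sparse outside it. In every library of wild-type and FTO_OE liver and of the 3 MEF lines, IP signal rose at the end of the leader and again around the end of the translated region. In wild-type fed liver replicate 1, IP signal in the last of 4 leader bins was 5.38 times the mean of the transcript, against 0.182 times in the input. In plain sufficient MEF the largest IP value, 2.80 times the mean, fell in the first of 10 trailer bins, and the last leader bin reached 1.28 times the mean. In the input of plain MEF, signal was lower over the translated region than over the trailer, at 0.498 times the mean in its last bin in sufficient cells and 1.76 times in the first bin of the trailer.

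**Figure D1:**
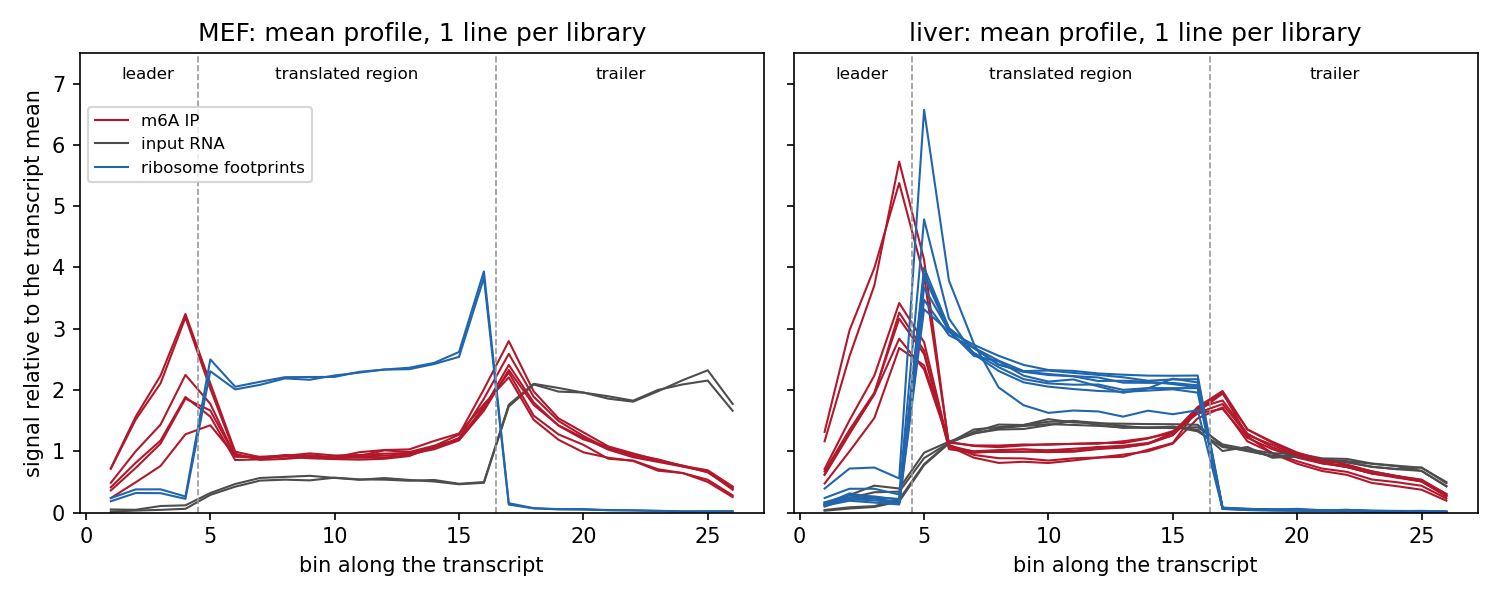
Mean profile of each library along transcripts with a leader, a translated region and a trailer, as signal relative to the mean of the transcript (y axis) in bins along the transcript (x axis), with 4 bins for the leader, 12 for the region and 10 for the trailer. Each line is 1 library, and IP lines peak at the leader end and at the region end, as in wild-type fed liver replicate 1 at 5.38 in the last leader bin.

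The first question was where m6A signal lies on MEF transcripts and whether it moves with starvation. Leaders held 6.14% of the IP signal in sufficient and 8.01% in starved plain MEF. They held 7.52% and 8.67% in shScram, and 12.3% and 11.6% in shALKBH5. Input leaders held 0.454% and 0.493% in plain MEF. The mean over the 3 lines was 9.44% ± 1.93 (SD, n = 3) in starved and 8.64% ± 3.21 (SD, n = 3) in sufficient cells, a difference of 0.797 percentage points (exact permutation test of the 6 libraries, two-sided p = 0.70, and the smallest p this design allows is 0.10). Within lines the differences had an SD of 1.29 (n = 3, exact sign-flip permutation test, p = 0.50, and the smallest p is 0.25). The mean difference was -0.453 without the plain sufficient and -0.300 without the shALKBH5 starved library. Per transcript, the leader ratio gave no call for starvation among 2695 transcripts in limma, with 125 at an unadjusted p below 0.05, and no other tool was run. The median log2 change was 0.12.

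**Figure D2:**
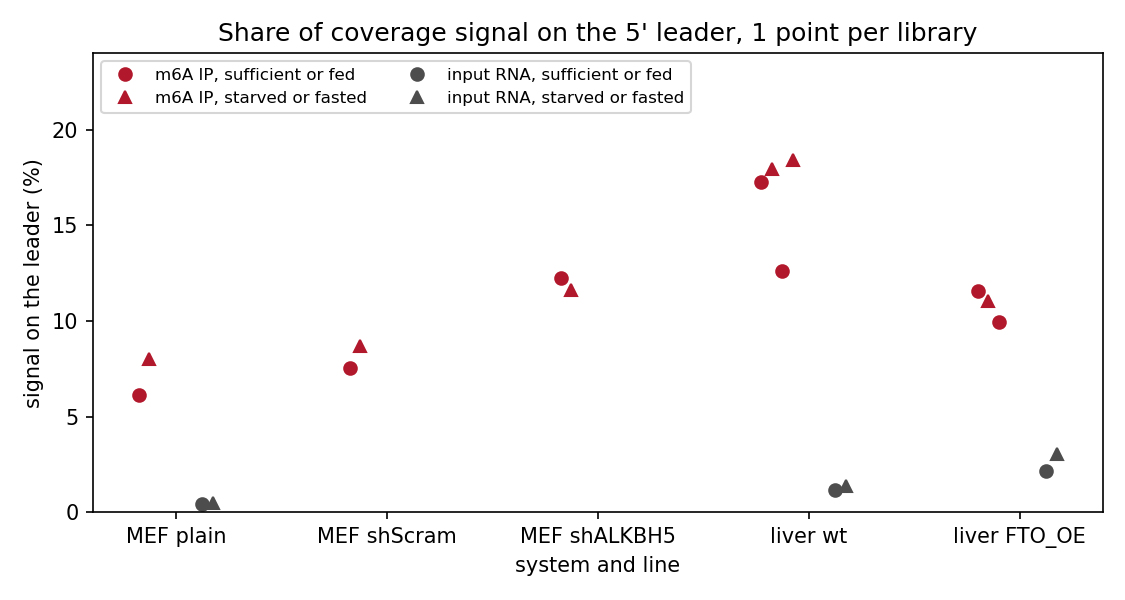
Share of coverage signal on the leader in percent (y axis) by system and line (x axis), 1 point per library, for IP and input RNA, with circles for sufficient or fed and triangles for starved or fasted. IP shares lie between 6.14% and 18.4%, and input shares between 0.454% and 3.07%.

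Leaders carried more of the IP signal in shALKBH5 MEF than in the other lines. The leader ratio was called in 444 of 2695 transcripts between shALKBH5 and shScram (2 libraries each), of which 394 were higher and 50 lower in shALKBH5, and the median log2 change over all transcripts was 0.47. ENSMUST00000111996 had the largest rise, at a log2 change of 3.62 (SE 0.51, adjusted p = 0.00669), followed by ENSMUST00000081079 at 3.36 (SE 0.49). ENSMUST00000109824 fell by 4.07 on the log2 scale (SE 0.44, adjusted p = 0.00460) and ENSMUST00000029142 fell by 3.95 (SE 0.45). The higher calls outnumbered the lower ones without any 1 of the 6 libraries, while the count of calls moved to 171 and 150 without the plain sufficient and plain starved library, 112 and 169 without the shScram sufficient and starved library, and 903 and 911 without the shALKBH5 sufficient and starved library.

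Whole-transcript IP signal of MEF changed with starvation in 105 of 11312 transcripts, of which 68 were higher and 37 lower, against 80 higher and 75 lower with RLE size factors. ENSMUST00000064795 rose most, from a mean log2 signal of 4.88 ± 1.07 (SD, n = 3) in sufficient to 9.68 ± 1.36 (SD, n = 3) in starved cells (log2 change 4.80, SE 0.20, limma adjusted p = 1.0e-05). ENSMUST00000021674 rose by 2.94 (SE 0.23, adjusted p = 0.000534). ENSMUST00000036937 fell by 2.05 on the log2 scale (SE 0.38, adjusted p = 0.0417) and ENSMUST00000078816 fell by 1.93 (SE 0.35). Between shALKBH5 and shScram, 2590 transcripts were called, 1133 higher and 1457 lower in shALKBH5. ENSMUST00000006956 was the highest, at a log2 change of 4.68 (SE 0.29, adjusted p = 0.000164), and ENSMUST00000118539 followed at 3.94 (SE 0.38). ENSMUST00000099931 fell by 3.38 (SE 0.32, adjusted p = 0.000512) and ENSMUST00000085133 fell by 3.25 (SE 0.39). These values are IP abundance and not enrichment, since shScram and shALKBH5 have no input here, and both counts went to 0 in limma when no filter on low signal was used, with 1384 and 4354 transcripts at an unadjusted p below 0.05. Without 1 library, starvation calls were 196 and 195 (plain sufficient, plain starved), 186 and 170 (shScram) and 822 and 821 (shALKBH5), and shALKBH5 calls were 1165 and 1139 without either shScram library and 4394 and 4345 without either shALKBH5 library.

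For plain MEF the IP could be set against its input, with 1 library for each, so no test was made and there was no replicate check. Enrichment differed at least 2-fold between starved and sufficient cells in 679 of 8096 transcripts, 388 higher and 291 lower. The largest difference was that of ENSMUST00000179285, at a log2 of 3.57. With a minimum of 50 reads in each library, 77 of 5268 transcripts differed at least 2-fold. Footprints of sufficient shALKBH5 and shScram MEF, 1 library each, differed at least 2-fold in 110 of 6550 transcripts, 62 higher and 48 lower in shALKBH5. ENSMUST00000198965 had 438 CPM (counts per 1000000 footprints) in shALKBH5 and 36.5 in shScram, and ENSMUST00000044250 had 40.2 and 172. Leaders held 1.96% of footprints in shALKBH5 (Wilson 95% interval 1.95 to 1.98) and 2.19% in shScram (2.18 to 2.20).

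Fasting changed footprints on the translated region in the liver of both genotypes. In wild type 319 of 7440 transcripts were called, 151 higher and 168 lower in fasted liver (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). ENSMUST00000113091 rose from a mean log2 level of 1.75 ± 0.29 (SD, n = 2) to 7.67 ± 0.77 (SD, n = 2), with an edgeR log2 fold change of 6.50 (SE 0.60, adjusted p = 0.00347). ENSMUST00000034585 rose by 5.39 (SE 0.74, adjusted p = 0.00640). ENSMUST00000029076 fell by 5.30 (SE 0.67, adjusted p = 0.00496) and ENSMUST00000169314 fell by 5.15 (SE 0.91, adjusted p = 0.0142). In FTO_OE liver 150 transcripts were called, 44 higher and 106 lower. ENSMUST00000113091 rose there as well, by 6.92 (SE 0.65, adjusted p = 0.00212), and ENSMUST00000103109 rose by 6.65 (SE 0.96). ENSMUST00000029464 fell by 8.09 (SE 1.34, adjusted p = 0.0166) and ENSMUST00000082214 fell by 5.75 (SE 1.20).

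The fasting effects of the 2 genotypes share no library. Their fold changes correlated across 7440 transcripts with Pearson's r = 0.706 and Spearman's rho = 0.647, where transcripts are not independent replicates. Both lists held 112 transcripts, each with the same direction in wild type and FTO_OE, against 6.43 for independent lists. The lists are not independent, since 1 fit gave both contrasts the same estimate of spread for each transcript, so 6.43 may be too low a reference. The interaction, which tests whether the fasting effect differed between genotypes, gave 0 calls in edgeR, with 217 transcripts at an unadjusted p below 0.05 and 0 calls in DESeq2. With the replicate number as a block, edgeR gave 2 calls for the interaction. In simulated data for the wild-type fasting contrast, 13.4% of log2 changes of 1 were called, so 0 calls do not show that the genotypes responded equally. DESeq2 called 706 transcripts in wild type and 316 in FTO_OE, and edgeR with the block called 614 and 242. Without 1 library, the wild-type count was 92 and 90 (fed replicates 1 and 2) and 1257 and 94 (fasted replicates 1 and 2). The FTO_OE count was 29 and 65 (FTO_OE fed replicates 1 and 2), 1 and 1 (FTO_OE fasted), and 264 and 264 (wild-type fasted).

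**Figure D3:**
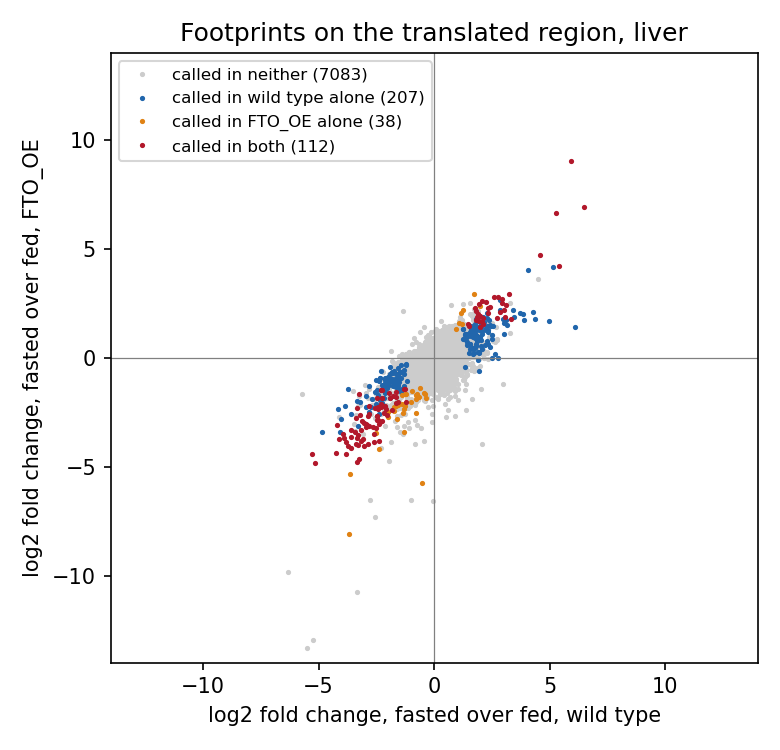
Log2 fold change of footprints on the translated region, fasted over fed, in wild type (x axis) and FTO_OE (y axis), 1 point per transcript. The 112 transcripts called in both lie in the quadrants of equal sign, 207 were called in wild type alone and 38 in FTO_OE alone.

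Input RNA changed with fasting in the same transcripts as footprints more often than independent lists would. Of 11137 transcripts, 728 were called, 325 higher and 403 lower in fasted liver. RLE size factors gave 459 higher and 424 lower, and the count was 1418 without the tallest 60 nt windows and 1309 without a filter. ENSMUST00000034585 rose in input as it did in footprints, by 4.71 (SE 0.22, limma adjusted p = 1.8e-06), and ENSMUST00000036765 rose by 4.70 (SE 0.19). ENSMUST00000108522 fell by 4.59 (SE 0.23, adjusted p = 1.8e-06) and ENSMUST00000096418 fell by 4.22 (SE 0.25). Of the calls in wild-type footprints 147 were also called in input, each in the same direction, against 21.1 for independent lists. For FTO_OE footprints the fold changes correlated with those of input at Pearson's r = 0.679, and for wild type at 0.607. Translational efficiency gave 0 calls for fasting in wild type among 7371 transcripts in limma, with 290 at an unadjusted p below 0.05, and no other tool was run. In simulated data for the FTO_OE contrast of that fit, 10.4% of log2 changes of 2 were called.

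The next comparison asked what FTO_OE did to footprints. In fed liver 0 of 7440 transcripts were called in edgeR, with 35 at an unadjusted p below 0.05, and 0 in DESeq2. In fasted liver 0 were called in edgeR, with 269 at an unadjusted p below 0.05, and 2 in DESeq2. With the replicate number as a block, edgeR called 3 in fed liver, all higher in FTO_OE, and 2 in fasted liver, both lower. Both unadjusted counts of the main fit were below the share of 0.05 that no effect would give, so that fit may be too strict here. In simulated data for the wild-type fasting contrast, 13.4% of log2 changes of 1 were called. The 0 calls therefore do not show that FTO_OE left footprints unchanged. The leader share of footprints was 1.30% ± 0.26 (SD, n = 4) in FTO_OE and 1.65% ± 0.70 (SD, n = 4) in wild type (exact permutation test, two-sided p = 0.457), and the FTO_OE minus wild-type difference of -0.351 percentage points was -0.0551 and -0.551 without wild-type fasted replicates 2 and 1. It was 1.49% ± 0.71 (SD, n = 4) in fasted and 1.46% ± 0.36 (SD, n = 4) in fed liver (exact permutation test, p = 0.943). Leader shares went with the replicate number, from 1.05% (Wilson 95% interval 1.04 to 1.06) to 1.17% (1.16 to 1.18) in the 4 libraries of replicate 1 and from 1.33% (1.31 to 1.35) to 2.54% (2.52 to 2.56) in those of replicate 2. The permutation tests took no account of the number. Fasted against fed, wild type had 1.05% against 1.15% in replicate 1 and 2.54% against 1.87% in replicate 2. FTO_OE had 1.06% against 1.17% and 1.33% against 1.65%. Wild-type fasted replicate 2 had the highest share, and the fasted minus fed difference was -0.313 percentage points without it. That difference was also below 0 without fed replicate 1 of wild type (-0.0688) or of FTO_OE (-0.0604).

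Input signal was higher in FTO_OE liver for many transcripts, and most of this signal lay in short windows. Of 11137 transcripts 702 were called, 676 higher and 26 lower in FTO_OE. ENSMUST00000085835 rose by 6.60 (SE 0.31, limma adjusted p = 3.9e-07) and ENSMUST00000011302 by 6.45 (SE 0.37). ENSMUST00000028010 fell by 1.13 (SE 0.18, adjusted p = 0.00242) and ENSMUST00000049178 fell by 1.12 (SE 0.19). The tallest 60 nt window held 99.8% of the signal of ENSMUST00000011302 in FTO_OE fed input and 46.5% in wild-type fed input, while ENSMUST00000085835 had at least 88.7% there in each of the 4 libraries. Over the transcripts called higher, the median share in that window was 86.1% and 89.9% in fed and fasted FTO_OE input and 9.48% and 16.1% in wild type, against 2.01% to 2.39% for other transcripts. With that window left out, 216 transcripts were called, 147 higher and 69 lower. Translational efficiency was called lower with FTO_OE in 7 transcripts in fed and 19 in fasted liver, among them ENSMUST00000011302, which fell by 7.45 in fed liver (SE 0.50, adjusted p = 0.000217), and ENSMUST00000193170, which fell by 6.88 in fasted liver (SE 0.71, adjusted p = 0.00446). No transcript was called higher, and both counts went to 0 in limma without the window, with 159 and 461 transcripts at an unadjusted p below 0.05.

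**Figure D4:**
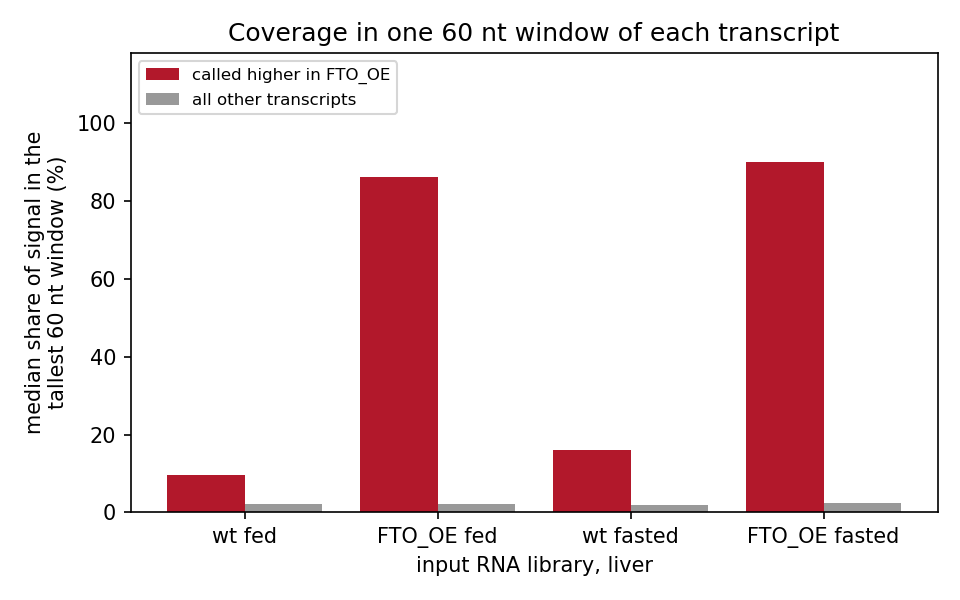
Median share of a transcript's signal in its tallest 60 nt window, in percent (y axis), in the 4 liver input libraries (x axis), for transcripts called higher in FTO_OE and for all others. The bars of called transcripts reach 86.1% and 89.9% in FTO_OE and 9.48% and 16.1% in wild type.

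IP enrichment of whole transcripts over input was compared next in liver. Among 10640 transcripts limma called 0 for fasting in wild type (46 at an unadjusted p below 0.05), 0 for FTO_OE in fed liver (275) and 0 for FTO_OE in fasted liver (216), and no other tool was run. With the replicate number as a block, 18 transcripts were called for FTO_OE in fed and 1 in fasted liver, all lower in FTO_OE. On the leader alone, with 4433 transcripts, 390 were called for fasting (128 higher, 262 lower), 561 for FTO_OE in fed liver (129 higher, 432 lower) and 358 for FTO_OE in fasted liver (115 higher, 243 lower). Each group had 1 input library with little signal on leaders, and 1 input read on a leader was enough to pass the filter. These leader calls can therefore reflect sparse input and do not by themselves show changes of m6A. Enrichment called 191 and 120 transcripts for FTO_OE in fed and fasted liver when low signal was not filtered.

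Leaders held less of the IP signal in FTO_OE than in wild-type liver. The share was 11.6%, 9.97% and 11.1% in the 3 FTO_OE libraries and 17.2%, 12.6%, 18.0% and 18.4% in the 4 wild-type libraries, with means of 10.9% ± 0.81 (SD, n = 3) and 16.5% ± 2.68 (SD, n = 4). The groups did not overlap, which 4 against 3 libraries reach at the smallest possible p of 0.0571 (exact permutation test, two-sided). Input shares went the other way, at 2.18% and 3.07% in FTO_OE and 1.17% and 1.40% in wild type. The groups overlapped without the 20 transcripts with most signal, without the 15 nt before the translated region, and without the tallest 60 nt windows, with differences of -4.54, -4.14 and -2.16 percentage points against -5.69 (exact permutation test, p = 0.114 for each). The median share per transcript overlapped as well, at 4.38% to 5.13% in FTO_OE and 4.39% to 10.2% in wild type (exact permutation test, p = 0.343). Within the same replicate number, FTO_OE was lower in 6 of 6 pairs by each of these 4 measures, and by the summed share, where the separation of the groups fixed this count. The pairs reuse the 3 FTO_OE and 4 wild-type libraries. Per transcript, the leader ratio gave 0 calls for FTO_OE among 2494 transcripts in limma, with 171 at an unadjusted p below 0.05 and a median log2 change of -0.38, and 160 calls with the replicate number as a block, 152 of them lower in FTO_OE. Fasting gave 15.8% ± 4.12 (SD, n = 3) against 12.8% ± 3.13 (SD, n = 4) in fed liver (exact permutation test, p = 0.343), where FTO_OE made up 1 of the 3 fasted and 2 of the 4 fed libraries. The difference of 2.96 percentage points was 0.758 for the median per transcript, 0.208 without the 20 transcripts with most signal and 0.695 without the tallest windows. It was 1.88 and 1.66 without wild-type fasted replicates 1 and 2 and 5.33 without the FTO_OE fasted library. The leader ratio gave 0 calls for fasting in limma, with 84 at an unadjusted p below 0.05 and 5 calls with the block.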

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

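The removal of the tallest windows, the comparison of input leaders, the comparison within replicate numbers and the regroupings of libraries were tests chosen only after the results were seen. The direction of the starvation effect on the leader share of IP signal differed between MEF lines. Starved minus sufficient was 1.87 percentage points in plain MEF and 1.15 in shScram, and -0.629 in shALKBH5. This difference between lines was not tested, with 1 library for each line and state.

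Of the 676 transcripts with higher input signal in FTO_OE liver, 399 were still measured without the tallest window. Still called higher were 83, which is 12.3% of the 676. The median log2 change was 1.98 over the 676 with the window and 0.24 (SD 0.75 across transcripts) over the 399 without it. For those 399 this argues against a higher RNA level along the whole transcript. Footprints of 159 of the 676 had a median log2 change of -0.02 between FTO_OE and wild type. A candidate explanation is fragments piled in 1 window, in FTO_OE input libraries whose isolated reads were shorter (medians 38 and 27 nt, against 42 and 39 nt in wild type). In FTO_OE IP the median share in the window was 33.0% and 71.3% in the 2 libraries of replicate 1 but 7.42% in replicate 2, against 4.84% to 14.5% in wild type, and the origin of these fragments was not tested.

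For the lower leader share of IP signal in FTO_OE liver, loss of leader fragments in the RNA itself is argued against by the input, where the leader share was higher in FTO_OE by at least 1.01 percentage points, and still higher without the tallest windows (1.12% and 1.28% against 0.671% and 0.800%). Both replicate numbers hold both genotypes, and FTO_OE was lower in 6 of 6 pairs of the same number. For the summed share the separation of the groups fixed this count, but not for the 4 measures whose groups overlapped, which also gave 6 of 6. The pairs reuse the 3 FTO_OE and 4 wild-type libraries, with 1 FTO_OE library of number 2. By the median share 1 pair was close to a tie, at 4.38% against 4.39%. A batch that follows the replicate number alone would not lower FTO_OE within a number, so the pairs argue against it for these libraries. The share around the region end, set up as a gauge of the IP, was 0.218 percentage points higher in FTO_OE, within its SD of 0.502, so weaker immunoprecipitation cannot be told apart from a change of the leaders. Without the tallest windows the FTO_OE mean was still lower, by -2.16 percentage points against -5.69 with them, while the groups overlapped across replicate numbers. Piled fragments may therefore account for part of the difference, and removal of m6A from leaders by FTO stays open as a hypothesis.

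For the higher leader share of IP signal in shALKBH5 MEF, stronger immunoprecipitation was expected to raise the share around the region end. That share differed by -3.01 percentage points from the other lines (pooled SD 1.76). Plain MEF, at 17.2% and 17.0%, carried most of this difference, with 13.5% and 13.7% in shScram and 12.3% and 12.4% in shALKBH5. Both shares are parts of the same signal, so a higher leader share by itself lowers the other, and stronger immunoprecipitation is not excluded. With no input for shScram and shALKBH5, a change of leader fragments in the RNA itself could not be examined. Piled fragments are argued against by the share without the tallest windows, which was still 3.50 percentage points higher (pooled SD 0.658), with 7.64% and 7.35% in shALKBH5 and 2.99% to 4.78% in the others. A candidate explanation is retained m6A on leaders when ALKBH5 is lowered, as a hypothesis found and weighed on these libraries. Other differences between the lines stay open and were not tested, as both libraries came from 1 knockdown line.

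Regroupings of libraries were counted for 4 results. For starvation and whole-transcript IP signal in MEF, the real split called 105 transcripts and the highest of the other splits called 1. The real split was the 1 with as many among 10, too few splits for a share under 0.05. Line was in the fit, so splits that kept both libraries of a line together rested on 1 line and are not like the real split. For starvation and the MEF leader ratio, the real split called 0, so each of the 10 splits gave as many, and the highest called 395. It was reached by the 2 splits that parted starved from sufficient in shALKBH5 alone, and 10 splits are too few for a share under 0.05. For the liver leader ratio the real splits for FTO_OE and for fasting called 0, so each of 34 splits had to give as many, and these counts decide nothing about chance. They were made without the replicate block, under which the real contrasts called 160 and 5 transcripts. The highest other splits called 419 and 375 where the real ones called 0, which points to a structure of the samples. The first set 3 of the replicate 1 libraries against the rest, and the second set the 3 replicate 2 libraries against the rest. Among the 16 other splits with as many replicate 2 libraries as the real one, the highest count was 0 for each.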

How the results depend on the processing

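The settings without the tallest 60 nt window, the test within MEF lines and all settings of the leader ratio were tests chosen after the data were seen. Of 284 alternative values, 205 stayed within 1.5 times the main count or kept their direction and side of the threshold, 74 counts moved further and 5 shares changed sign. The cause was not tested where none is given. With the replicate number as a block, calls for footprints went to 614 and 242 for fasting in wild type and FTO_OE, 3 and 2 for FTO_OE in fed and fasted liver and 2 for the interaction. The deviations of Ribo-seq replicates correlated between -0.0913 and 0.445 across groups, at 0.288 or more in 3 of 6 pairs of groups, so the rule for pairing was not met over all pairs. The pairs of groups in the FTO_OE contrasts were among the correlated ones, at 0.445 in fed and 0.343 in fasted liver. For these contrasts the main fit thus left out a pairing that the libraries show. Reading frame and leader share did go with the number, so the blocked counts stand beside the main ones. The block gave 18 and 1 calls for IP enrichment with FTO_OE in fed and fasted liver, and 160 and 5 for the liver leader ratio with FTO_OE and fasting. Translational efficiency with FTO_OE had 10 and 26 calls with the block in fed and fasted liver, against 7 and 19, and translational efficiency and IP enrichment with fasting stayed at 0. DESeq2 called 706, 316 and 2 transcripts for fasting in wild type, fasting in FTO_OE and FTO_OE in fasted liver, and 0 for the other footprint contrasts. Without a filter, IP enrichment called 191 and 120 with FTO_OE in fed and fasted liver, input called 1309 with fasting and 1529 with FTO_OE, and MEF IP signal called 0 for starvation and 0 for shALKBH5. With a filter at 5 per 1000000, input called 418 with FTO_OE. On the leader alone, where 1 input read passed the filter, enrichment called 390, 561 and 358 for fasting, FTO_OE in fed and FTO_OE in fasted liver. IP without input called 3 for fasting. Without the tallest 60 nt window, translational efficiency called 0 and 0 with FTO_OE in fed and fasted liver, input called 1418 with fasting and 216 with FTO_OE, and the leader ratio called 3 with fasting. With a pseudocount of 4 the MEF leader ratio called 2 for starvation and 677 for shALKBH5. With at least 50 reads, 77 transcripts differed 2-fold in MEF enrichment, fewer being compared. Transcript groups had 11 calls with the preset correlation, 0 with an estimated correlation and 2 with fry.

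With 1 library left out, counts ran from 90 to 1257 and from 1 to 264 for fasting footprints in wild type and FTO_OE, from 0 to 1 for FTO_OE in fasted liver, and stayed at 0 for FTO_OE in fed liver and the interaction. The extremes were without wild-type fed replicate 2, wild-type fasted replicate 1 and either FTO_OE fasted library. Translational efficiency with FTO_OE in fed liver gave 3 without FTO_OE fed replicate 2, 4 without wild-type fed replicate 1 or either FTO_OE fasted library, and 11 without either wild-type fasted library. In fasted liver it gave 4 and 3 without FTO_OE fasted replicates 1 and 2 and 39 without wild-type fasted replicate 1. Enrichment with FTO_OE in fed liver ran from 0 to 40 (without FTO_OE fed replicate 1). MEF IP signal ran from 170 to 822 for starvation and 1139 to 4394 for shALKBH5, and the leader ratio from 0 to 2 for starvation and 112 to 911 for shALKBH5, each highest without a shALKBH5 library. The fasted minus fed leader share of footprints ran from -0.313 to 0.183 percentage points. It was -0.0688 and -0.0604 without fed replicate 1 of wild type and of FTO_OE, and -0.313 without wild-type fasted replicate 2. The starved minus sufficient leader share of MEF IP signal ran from -0.453 (without plain sufficient) to 2.61, and was -0.300 without shALKBH5 starved. An arm left with 1 library was assumed to vary like the others. DESeq2 was not run for coverage signal, for translational efficiency or for enrichment, and no library could be left out of the liver input fits, which then have no residual degrees of freedom. The replicate number could not serve as a block for MEF and liver input because each group there has 1 library, and these fits had line or genotype as an additive effect. Within MEF lines the starvation difference of the leader share was 0.797 percentage points as before (exact sign-flip permutation test, p = 0.50). No library could be left out of single-library comparisons. Depth limits the FTO_OE fed replicate 2 footprints most, at 732452.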

Other observations

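The transcript groups in this part, their medians with 1 wild-type fasted library, the tests of leader m6A signal against footprints and the test on the single transcript were chosen only after the results were seen, while camera, its estimated correlation and fry had been planned for gene lists. Transcripts were grouped by properties seen in the same libraries: a leader with at least 10% of footprints, a leader, trailer or region in the longest 25%, a region under 450 nt, and footprints at least 32 times higher in liver than in MEF or at least 8 times higher in MEF than in liver. Transcripts with higher footprints in MEF were lower in fasted FTO_OE liver, with 42 of 776 called lower, 0 called higher and a median log2 change of -0.63 against 0.04 for all others (camera adjusted p = 3.4e-13, and adjusted p = 0.122 with an estimated correlation). In wild type 45 of them were called lower and 5 higher, with a median of -0.12 (camera adjusted p = 0.0872). In input 37 of 674 were called lower and 4 higher with fasting (camera adjusted p = 0.0155, and adjusted p = 0.983 with an estimated correlation). Between FTO_OE and wild type in fasted liver their median was -0.32 (camera adjusted p = 7.3e-08, and adjusted p = 0.0644 with an estimated correlation), and in fed liver it was 0.13. Wild-type fasted replicate 2 stood apart, with a Spearman correlation of 0.903 with its own replicate against 0.966 and 0.971 of that replicate with the FTO_OE fasted libraries. From mean log2 CPM, the median FTO_OE minus wild-type change of this group was -0.25 with both wild-type fasted libraries, -0.17 with replicate 1 alone and -0.32 with replicate 2 alone.

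In fed liver, footprints of transcripts with a region in the longest 25% had a median log2 change of -0.08 with FTO_OE against 0.02 for the others (camera adjusted p = 0.000834, and adjusted p = 0.421 with an estimated correlation). Transcripts higher in liver (median 0.06), those higher in MEF (0.13), those with a region under 450 nt (0.07) and those with at least 10% of footprints on the leader (0.08) were called higher there by camera, and each of these calls was lost with an estimated correlation (adjusted p = 0.421). Input in FTO_OE liver was called lower for transcripts higher in liver (median -0.11), for a region under 450 nt (-0.11) and for the longest trailers (-0.12), with adjusted p of 0.717 to 0.731 with an estimated correlation. Of 56 tests 11 passed with the preset correlation and 0 with an estimated one. With fry 2 passed, both for lower footprints in fasted FTO_OE liver, in transcripts higher in MEF and in those with the longest trailers (adjusted p = 0.0308 for each). None of the 7 groups passed camera for starvation or shALKBH5 in MEF IP signal.

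A hypothesis that transcripts with a gain of leader m6A signal in shALKBH5 MEF also gained footprints, measured in sufficient cells alone, was tested across 2654 transcripts. Spearman's rho was -0.0444, where 0.1 had been set as the bound, and the 391 transcripts called higher for the leader ratio had a median footprint log2 difference of -0.00. The hypothesis that transcripts with a loss of leader m6A signal in FTO_OE liver lost footprints was tested across 2493 transcripts, with a rho of -0.0242. The measured changes in MEF thus showed no relation of that size across these transcripts, which are not independent replicates. With 1 Ribo-seq library per line and no input for these lines, noise in both changes can weaken rho, so a relation is not excluded. In liver neither change had a call in the main fits, which had no block for the replicate number. With the block the leader ratio had 160 calls, but rho was taken from changes without it, so the value there decides nothing.

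Only 1 of 7440 transcripts, ENSMUST00000069718, had footprints more than 1 log2 unit higher in every FTO_OE liver library than in every wild-type one. Its mean log2 CPM of footprints were 7.88 ± 0.15 (SD, n = 4) in FTO_OE and 6.44 ± 0.22 (SD, n = 4) in wild type. All 4 FTO_OE libraries lay above all 4 of wild type in 16 transcripts and below in 9. Both counts are fewer than the 106 expected for each if the libraries were exchangeable. The libraries were not exchangeable, since each genotype held fed and fasted libraries of both replicate numbers, which spread its values. These counts therefore decide nothing about an FTO_OE effect on many transcripts. A candidate explanation is an added copy that holds the coding region without the trailer. Input signal of this transcript was 2.94 and 2.44 times higher in FTO_OE over the translated region, in fed and fasted liver, and 1.29 and 1.24 times over the trailer. The ratio of these was 2.28 in fed and 1.96 in fasted liver, and the bound of 2 set for both was not reached in fasted liver. IP signal per 1000000 was 38.4 to 72.2 over the region in the 3 FTO_OE libraries and 10.9 to 27.5 in the 4 of wild type, and 6.71 to 7.41 against 4.06 to 5.88 over the trailer. These IP values go against a rise of equal size along the whole transcript, though IP signal also depends on m6A, and the added copy stays open.

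Footprints of replicate 1 and replicate 2 of liver differed in reading frame. The median share of footprints in the main frame was 56.7% to 62.9% in the 4 libraries of replicate 1 and 47.1% to 47.8% in those of replicate 2, and 47.3% and 47.1% in the MEF libraries. Within the first bin of the translated region, wild-type fasted replicate 2 had 6.57 times the mean of the transcript, and the other liver libraries had 3.32 to 4.78 times. The share of IP signal within 100 nt of the region end was 12.3% to 17.2% in MEF against 6.96% and 7.61% in input, and 9.98% to 11.3% in liver IP against 8.97% to 10.6% in input.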
